A study of Homo sapiens with 32 samples.

How the data were processed

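RNA from 32 human skin biopsies was sequenced. Per the labels, 7 biopsies came from skin with sclerotic chronic graft-versus-host disease, 10 from lesional and 7 from non-lesional skin of people with atopic dermatitis, and 8 from healthy skin. The biopsies came from 25 donors, and 7 of the 10 donors with atopic dermatitis gave both a lesional and a non-lesional biopsy. Total RNA was extracted with a miRNeasy kit and libraries were made with a stranded kit that selects polyadenylated RNA, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.9.1, STAR 2.4.2a, featureCounts 1.5.0-p2, edgeR and limma, and the human genome build GRCh37. They give these names without the settings used, so the strand setting of the counting is not known.

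The authors deposited 2 tables. The first holds voom-transformed values, which are on a log2 CPM (counts per M reads) scale, for 20536 genes. The second deposited table holds TPM (transcripts per M transcripts) for 33642 genes. All columns of both tables were matched to samples by title, and 0 columns were left unmatched. The log2 values were checked for whole reads: among values that stood for fewer than 50 reads, 100% lay within 0.02 of a whole number in every sample. The total of the recovered reads ranged from 38.98 to 144.97 M (mega) reads per biopsy, with a median of 54.085 M reads. XIST and Y-linked genes, 40 in the first table and 126 in the second, were left out of all tests and tables. This left 20496 genes for testing, of which 19400 also had a TPM row. Dates stood in place of gene names in 26 rows of the voom values, so their genes entered the tests but are not named.

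Genes were compared between groups with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on the deposited log2 values. The model held all 32 biopsies with 1 coefficient per group and no covariate. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 20496 genes, and a gene was called at an adjusted p below 0.05. The precision weights of voom are not part of the deposited table, so the trend stood in for them. Levels are means and SDs of the deposited TPM, and the test is always that on the log2 values. The 14116 genes found only in the TPM table were tested with limma on log2(TPM + 1). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

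A total of 39 gene lists for immune axes, matrix, epidermis, signs of RNA quality and skin cell types were written before the data were examined, as were the tests, the rule for naming genes and most alternatives. Each list was tested with camera from limma with a preset inter-gene correlation of 0.01, adjusted over the 39 lists within a comparison. Camera with a correlation estimated from the data and fry were run beside it. With the estimated correlation, 0 lists were called in any of the 6 comparisons. With the preset correlation, random regroupings of the biopsies called a median of 13 to 17 of the 39 lists, depending on the comparison. A call with the preset correlation is therefore weak evidence by itself. List members were also counted "adjusted over the list alone". A list needed 3 measured genes.

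The named genes follow a rule. For each comparison these are the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change, among genes with a mean TPM of at least 1 in either group. Immunoglobulin and T cell receptor segments and unnamed loci were left out of that rule. To these were added, for each list described, its 3 passing members with the largest absolute fold change, and a fixed set of immune, barrier and matrix genes. Some genes that the rule or the set would name are not reported here, though they still count as members of their lists. A gene at 0 in most biopsies of a group is given as such, with no fold. Genes with near-identical copies share reads, so the values of SPRR2 family genes, DEFB4A, S100A7A, KRT6C, FCGR1A, FCGR3A and the pseudogenes named are uncertain. The same holds for ZNF667-AS1, which overlaps another gene.

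Of the atopic dermatitis donors, 7 gave both biopsies. The pairing comes from the labels, so the comparison of lesional with non-lesional skin was also fitted with the donor as a block. In one such fit the donor was a random block over all biopsies, with a consensus correlation of 0.63. In another it was a fixed block over the 7 donors with both biopsies.

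The test was tried on simulated data with the mean of each gene over all 32 biopsies and with their library sizes, compared as sclerotic against healthy skin. Genes were simulated independently of each other. Among 20496 genes, 200 were changed, far fewer than the 4083 called in the real data, so the shares hold for that setting. The test recovered 41% of genes changed 2-fold and 74% of those changed 4-fold, and 3.36% of its calls were unchanged genes. With no change simulated it made 0 calls.

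The alternatives covered other values (log2 of TPM with 1 or 0.1 added, median-centred samples, quantile normalization), another set of genes, and other models (robust fit, array weights, only the groups compared, donor block). A minimum absolute log2 fold change of 1 and leaving out each biopsy in turn were also tried. Voom precision weights from the recovered reads, a correction for GC content and gene length, and the mean of the adipocyte list as a covariate were chosen only after the data had been seen. The annotation at hand, GENCODE 29, uses a later genome build than the authors, so no coordinates are given and GC content and length were joined by gene name. They were found for 17114 of the 20496 genes (83.5%), and 13954 genes were corrected. To see what chance gives, the samples of each comparison were regrouped into groups of the same sizes 100 times, the real grouping included, with 64 swaps within donors for the paired fits.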

Results

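Gene expression was measured by RNA sequencing in 32 skin biopsies: 7 with sclerotic chronic graft-versus-host disease, 10 from lesional and 7 from non-lesional skin in atopic dermatitis, and 8 from healthy skin. Sclerotic chronic graft-versus-host disease is a hardening of the skin after a transplant of blood-forming cells, and atopic dermatitis is the common form of eczema. The totals recovered per biopsy, in M (mega) reads, were 58.0 ± 10.2 M reads (SD, n = 7) in sclerotic skin and 59.9 ± 17.2 M reads (SD, n = 10) in lesional skin. They were 68.0 ± 36.9 M reads (SD, n = 7) in non-lesional skin and 48.7 ± 8.29 M reads (SD, n = 8) in healthy skin. Mitochondrial genes took 24.8 ± 5.90% of TPM in sclerotic, 18.7 ± 5.88% in lesional, 23.0 ± 5.69% in non-lesional and 27.6 ± 7.70% in healthy skin. The first 2 principal components held 19.6% and 14.4% of the variance. The study asked which inflammatory axes were active in sclerotic skin, with interest in type 1 helper T cell (Th1) signals and in the pair formed by TSLP, a cytokine of epithelial cells, and OX40, a costimulatory receptor of T cells. All adjusted p-values for genes are from limma.

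**Figure D1:**
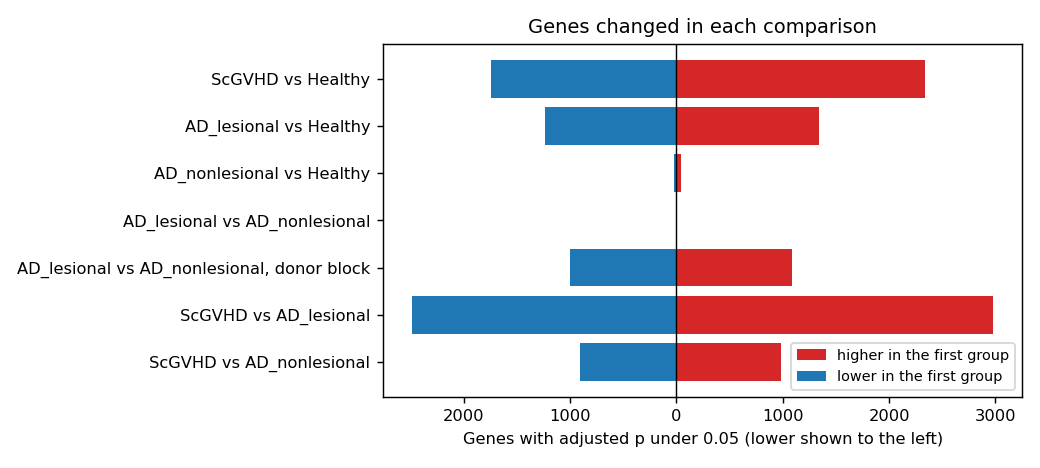
Numbers of genes called by limma at an adjusted p below 0.05 in each comparison, with bars to the right for genes higher and bars to the left for genes lower in the first group. The total goes from 0 for lesional against non-lesional skin without the donor block, which has 2093 with it, to 5467 for sclerotic against lesional skin.

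The first comparison asked how sclerotic skin differed from healthy skin. Chemokines that interferon-gamma induces and that draw T cells were far higher: CXCL9 was at 115 ± 132 TPM (SD, n = 7) in sclerotic and 2.13 ± 1.56 TPM (SD, n = 8) in healthy skin, and 32.5-fold higher by the fitted log2 fold change. TSLP and the OX40 ligand gene TNFSF4 were also higher, as were 11 of 16 macrophage markers, 13 of 27 matrix genes and 10 of 13 adipocyte genes, whereas 7 of 20 hair follicle and 6 of 13 sebaceous gland genes were lower. Limma called 4083 of 20496 genes, 2338 higher and 1745 lower, and 1603 of them had an absolute log2 fold change of at least 1. With the mean of the adipocyte list as a covariate it called 1571, 1095 higher and 476 lower. The split between higher and lower depended on the scale: it was 1696 higher and 2377 lower with each biopsy centred on its median, and 2079 higher and 768 lower on log2(TPM + 1).

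Of the Th1 and interferon-gamma axis, 11 of 17 measured members rose over all genes, 6 did not pass, and 13 rose adjusted over the list alone. Camera called the list higher (adjusted p = 5.04e-07), but not with an estimated correlation (adjusted p = 0.539 with an estimated correlation). CXCL9 rose by 5.02 on the log2 scale (SE 0.98, adjusted p = 0.000725), and CXCL11, which acts on the same receptor, by 4.49 (SE 0.93, adjusted p = 0.00128). CXCL10 rose by 3.53 (SE 1.06, adjusted p = 0.0195), a call that was lost without ScGVHD replicate 5 (2.92, adjusted p = 0.0538). IFNG, the gene of interferon-gamma itself, was listed at 0 in 6 of 8 healthy biopsies and at 1.67 ± 2.21 TPM (SD, n = 7) in sclerotic skin, with an adjusted p of 0.0022. The chemokine gene CCL5 rose by 2.39 (SE 0.6, adjusted p = 0.0063), whereas IL12RB1 differed by 1.41 with an adjusted p of 0.0511 and was called without ScGVHD replicate 4 (1.68, adjusted p = 0.0194), 6 or 7 or Healthy replicate 6 or 7. Antigen presentation and interferon-gamma induced enzymes rose in 10 of 23 members over all genes and 15 adjusted over the list alone, led by IDO1 (2.92), GBP5 (2.69) and GBP4 (2.59). Type I interferon-stimulated genes rose in 10 of 23 members and 11 adjusted over the list alone, with IFI27 at 2.10, OAS2 at 1.89 and IFI44L at 1.82. Camera called both lists higher (adjusted p = 1.47e-06 and 5.08e-05), and each had an adjusted p = 0.539 with an estimated correlation.

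Among the 9 members of the TSLP and OX40 axis, 3 rose and 6 did not pass, over all genes and adjusted over the list alone. TNFSF4, which encodes the ligand of OX40, rose by 2.19 (SE 0.43, adjusted p = 0.000728), from 0.476 ± 0.148 TPM (SD, n = 8) to 2.90 ± 2.31 TPM (SD, n = 7). TSLP rose by 1.79 (SE 0.38, adjusted p = 0.00162), from 0.556 ± 0.295 TPM (SD, n = 8) to 1.95 ± 0.796 TPM (SD, n = 7), and the adaptor TRAF5 by 0.88 (SE 0.21, adjusted p = 0.00398). The OX40 gene TNFRSF4 differed by 0.47 (adjusted p = 0.615), the TSLP receptor gene CRLF2 by -0.33 (adjusted p = 0.728) and IL7R by 0.06 (adjusted p = 0.959). The list as a whole was not called (camera adjusted p = 0.154, and adjusted p = 0.675 with an estimated correlation). JAK-STAT components rose in 6 and fell in 1 of 16 members, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.11, and adjusted p = 0.539 with an estimated correlation).

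Members of the type 2 helper T cell (Th2) axis moved both ways: 2 rose, 3 fell and 12 did not pass, and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0811, and adjusted p = 0.539 with an estimated correlation). The Th2 chemokine CCL17 fell by 3.12 (SE 0.83, adjusted p = 0.00901), CCL22 fell by 2.00 (SE 0.72, adjusted p = 0.0483), and the Th2 transcription factor GATA3 fell by 1.72. The alarmin IL33 rose by 1.07 and IL13RA1 by 0.49. IL13 differed by -1.35 (adjusted p = 0.177), CCL18 by 0.18 (adjusted p = 0.924), CCL26 by -1.52 (adjusted p = 0.15) and IL4R by 0.24 (adjusted p = 0.537). The call of CCL22 was lost in 11 of 15 fits that left out 1 biopsy. In the Th17 and Th22 axis, 1 of 24 members fell and 0 passed adjusted over the list alone, with a median log2 fold change of 0.21 and a mean of -0.04 (camera adjusted p = 0.652, and adjusted p = 0.908 with an estimated correlation). S100A8 differed by 0.32 (adjusted p = 0.907), and IL22 was listed at 0 in 6 of 8 healthy and 6 of 7 sclerotic biopsies.

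Macrophage and monocyte markers rose in 11 of 16 members over all genes and in 14 adjusted over the list alone, with a median log2 fold change of 2.08 (camera adjusted p = 1.29e-06, and adjusted p = 0.539 with an estimated correlation). The Fc receptor gene FCGR1A rose by 4.36 (SE 0.8, adjusted p = 0.000416), the mannose receptor gene MRC1 by 3.74 and the scavenger receptor gene MSR1 by 3.23. Cytotoxic T and NK cell genes rose in 6 of 16 members and 8 adjusted over the list alone, among them GZMH (2.97), KLRD1 (2.87) and GZMA (2.65), while GZMB differed by 2.21 (adjusted p = 0.0849) and was called without ScGVHD replicate 4 (2.63, adjusted p = 0.0415). B and plasma cell genes rose in 4 of 14 members by either adjustment, led by CD38 (2.98), IGJ (2.75) and PAX5 (2.55). Both lists were called by camera (adjusted p = 0.000296 and 0.00783), with adjusted p = 0.539 and 0.541 with an estimated correlation. General T cell genes were called as a list (adjusted p = 0.0332, and adjusted p = 0.709 with an estimated correlation), although 0 of 15 members passed.

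Fibrillar collagen and matrix genes rose in 13 of 27 members over all genes and 15 adjusted over the list alone (median 1.00, camera adjusted p = 1.28e-05, and adjusted p = 0.539 with an estimated correlation). SFRP4, a modulator of Wnt signals, rose by 3.71 (SE 0.92, adjusted p = 0.00554), the metalloprotease gene ADAM12 by 2.06 and COMP, a matrix protein gene, by 2.01. The main dermal collagens did not pass: COL1A1 differed by 0.39 (adjusted p = 0.744) and COL3A1 by 0.75 (adjusted p = 0.442). The TGF-beta axis rose in 7 of 17 members and 9 adjusted over the list alone (camera adjusted p = 8.24e-05, and adjusted p = 0.539 with an estimated correlation). Its passing members included the activin subunit gene INHBA (1.92) and the feedback gene SKIL (1.71), while TGFB1 differed by 0.13 (adjusted p = 0.735) and CTGF by 1.10 (adjusted p = 0.0692), which was called without ScGVHD replicate 4 (1.28, adjusted p = 0.0373) or 6 or Healthy replicate 6. Matrix remodelling enzymes had 0 of 16 members past the threshold, with a list call of adjusted p = 0.024, and adjusted p = 0.539 with an estimated correlation.

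Markers of tissue parts moved as well. Adipocyte genes rose in 10 of 13 members by either adjustment (median 3.54, camera adjusted p = 1.28e-05, and adjusted p = 0.539 with an estimated correlation), led by LEP (5.33), ADIPOQ (5.18) and CIDEC (4.5), and C14orf180, outside that list, rose by 4.68. LEP lost its call without ScGVHD replicate 3 (adjusted p = 0.0554) or 7 (adjusted p = 0.0528), and CIDEC in 4 and C14orf180 in 2 of 15 fits that left out 1 biopsy. Sebaceous gland genes fell in 6 of 13 members and 11 adjusted over the list alone, with AWAT2 lower by a log2 fold change of -6.0, DGAT2L6 at -5.67 and PNPLA5 at -5.53. Hair follicle genes fell in 7 of 20 members and 16 adjusted over the list alone, with KRT25 at -7.07 and KRT85 at -5.83, and KRT83 at 0 in 5 of 7 sclerotic biopsies. Camera called both lists lower (adjusted p = 5.65e-05 and 2.08e-06), each with an adjusted p = 0.539 with an estimated correlation. CYP4F8 fell by 6.39 and the hair keratin-associated gene KRTAP11-1 fell by 5.96, while KRTAP3-1 was at 0 in 4 of 7 sclerotic biopsies. Calls of AWAT2, KRTAP11-1 and KRTAP3-1 were lost in 11 of 15 fits without 1 biopsy, and those of KRT25, KRT85 and DGAT2L6 in 10. The defensin gene DEFB132 was called higher and was listed at 0 in 7 of 8 healthy biopsies.

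The vessel and nerve lists were called higher too. Smooth muscle and pericyte genes rose in 5 of 13 members by either adjustment, with SYNPO2 at 1.76, and blood endothelium genes in 4 of 12 members and 8 adjusted over the list alone, with TEK at 1.36. Lymphatic endothelium rose in 3 of 6 members by either adjustment, with PROX1 at 1.67, and Schwann cell genes in 1 of 10, CDH19 at 1.97. Neutrophil and eosinophil genes rose in 1 of 9 members, FPR2 at 3.49, and 3 adjusted over the list alone. Camera gave these 5 lists adjusted p = 0.00169, 0.00392, 0.0412, 0.0283 and 0.028. Each was at adjusted p = 0.539 with an estimated correlation, except Schwann cells at adjusted p = 0.541. With the mean of the adipocyte list as a covariate, the smooth muscle median was 0.53 in place of 1.23, the endothelial median 0.28 in place of 0.74 that of the TGF-beta axis 0.34 in place of 0.56 and that of the sweat gland list -2.64 in place of -1.65. Immediate-early and heat-shock genes, which react to handling and stress, fell in 8 of 17 members and 10 adjusted over the list alone, with FOSB at -2.61, FOS at -2.3 and NR4A1 at -1.92 (camera adjusted p = 2.49e-05, and adjusted p = 0.539 with an estimated correlation). Ribosomal protein genes (3 of 30 fell, 1 adjusted over the list alone), sweat gland genes (1 of 12 fell, MUCL1 at -3.71) and proliferation genes (2 of 14 fell, MCM2 at -0.99 and MCM5 at -0.64) were called lower. Their camera adjusted p-values were 0.000263, 0.00308 and 0.028, with adjusted p = 0.621, 0.539 and 0.675 with an estimated correlation.

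The epidermal barrier showed no call in this comparison: 0 of 28 cornified envelope genes passed (camera adjusted p = 0.52, and adjusted p = 0.908 with an estimated correlation). Filaggrin, FLG, was at 804 ± 509 TPM (SD, n = 7) against 632 ± 341 TPM (SD, n = 8) with an adjusted p of 0.637, and loricrin, LOR, differed by -0.07 (adjusted p = 0.972). Basal and spinous keratinocyte genes rose in 1 and fell in 1 of 16 members, with a median of -0.46, or -0.01 with the adipocyte covariate (camera adjusted p = 0.0632 without it, and adjusted p = 0.675 with an estimated correlation). Of 14 fibroblast markers, 0 passed, with a median of 0.04. Fold changes fell with the GC content of genes, at a correlation across genes of -0.39 over 13954 genes, and genes are not independent replicates. With GC content and length corrected, 1713 of these 13954 genes were called, and 3548 without the correction. After it, 3 of 23 interferon-stimulated genes were called, with a median of 1.08 in place of 1.13, 9 of 27 matrix genes (0.98 in place of 1.00), 2 of 17 stress genes (-0.78 in place of -0.87) and 5 of 10 Th1 genes (1.36 in place of 1.57). It called 12 of 23 antigen presentation, 11 of 13 macrophage, 7 of 17 TGF-beta and 5 of 11 endothelial genes, with medians of 0.74, 1.95, 0.57 and 0.88 in place of 0.92, 2.08, 0.56 and 0.74. Of smooth muscle genes it called 3 of 13, with a median of 1.07 in place of 1.23. The medians without the correction cover all measured members, while the corrected ones leave out members without GC content and length or with low values. The Th1 list went from 17 to 10 members and the macrophage list from 16 to 13. Differences in such lists cannot be credited to the correction alone.

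**Figure D2:**
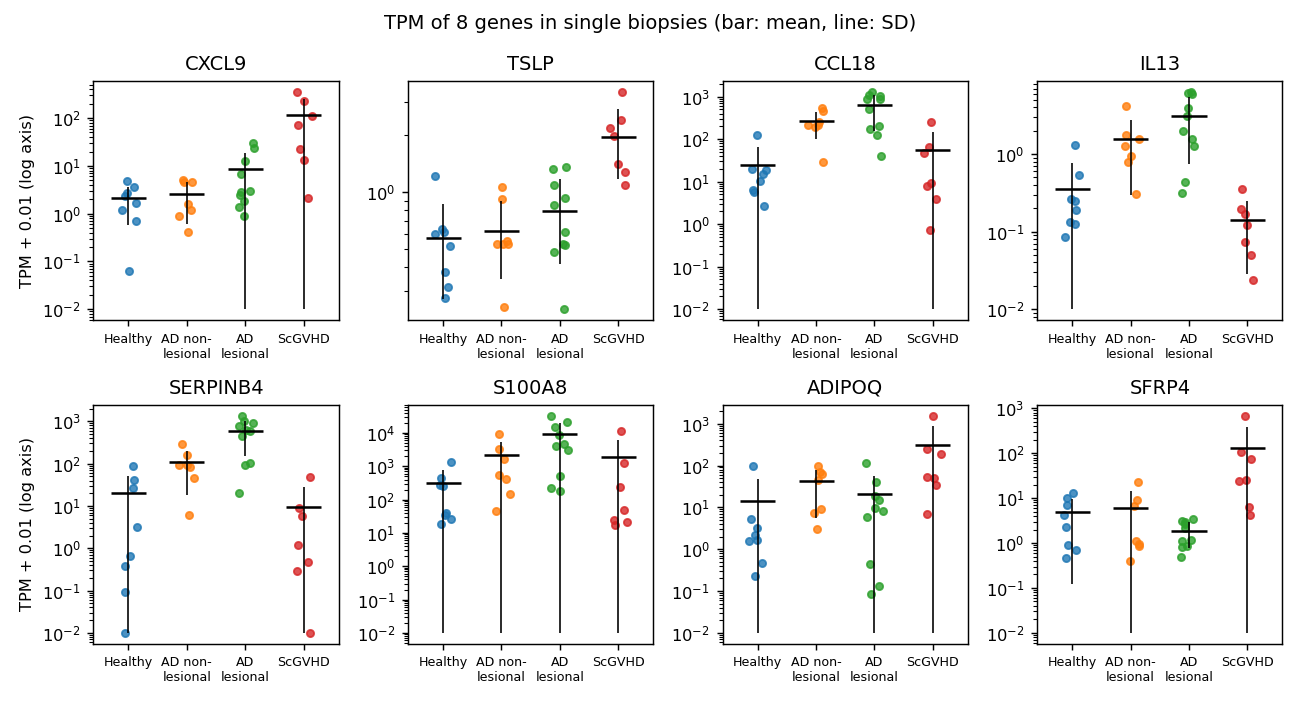
TPM with 0.01 added (log axis) of 8 genes in single biopsies by group, with points for the 32 biopsies, horizontal bars for the means and vertical lines for the SDs, which end at 0.01 where the mean less the SD is below it. CXCL9 averages 115 TPM in sclerotic, 8.47 in lesional, 2.62 in non-lesional and 2.13 in healthy skin, and CCL18 averages 56.1, 621, 273 and 25.0.

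**Figure D3:**
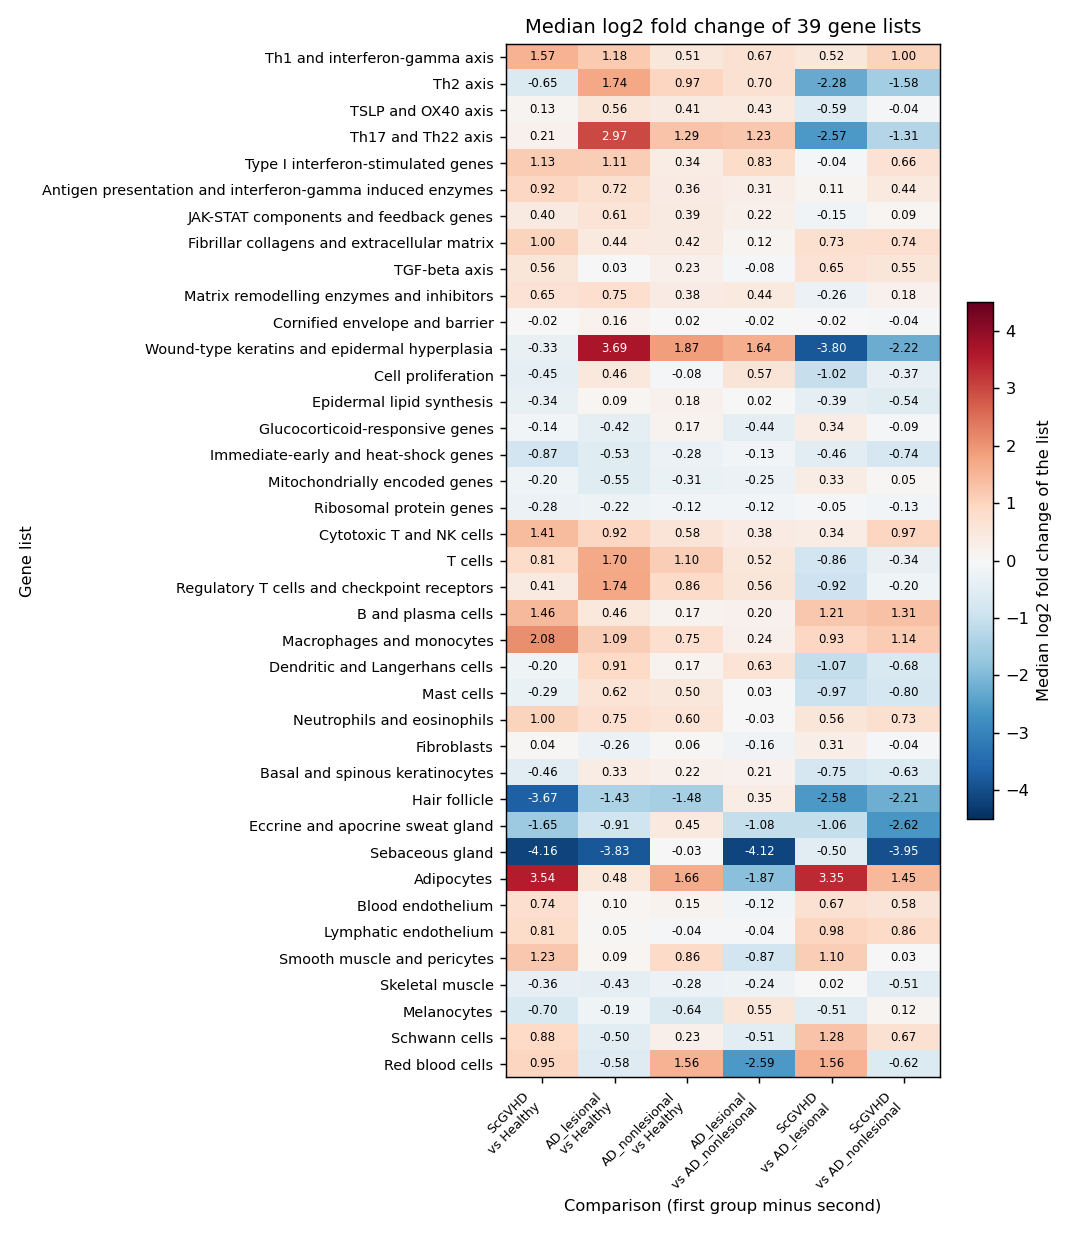
Median log2 fold change of the members of each of 39 gene lists (vertical axis) in each comparison without the donor block (horizontal axis), as colour and printed value. The Th1 list is at 1.57 in sclerotic and 1.18 in lesional skin against healthy skin, and the Th2 list is at -0.65 and 1.74.

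The second comparison, of lesional atopic skin with healthy skin, gives the profile of an established Th2 disease as a reference. The Th2 chemokine CCL18 was at 621 ± 465 TPM (SD, n = 10) in lesional and 25.0 ± 39.6 TPM (SD, n = 8) in healthy skin, and 33.5-fold higher by the fitted log2 fold change. Of the genes of a thickened, wound-type epidermis 10 of 14 were higher, with SERPINB4 at 597 ± 445 TPM (SD, n = 10) against 20.2 ± 32.2 TPM (SD, n = 8). Of T cell genes 10 of 15 were higher and of regulatory T cell and checkpoint genes 8 of 13, and 5 of 13 sebaceous gland genes were lower. Limma called 2586 genes, 1345 higher and 1241 lower, of which 1066 had an absolute log2 fold change of at least 1. On log2(TPM + 1) the split was 561 higher and 794 lower, and without AD_lesional replicate 2 the count was 1656.

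Over all genes, 10 of 17 members of the Th2 axis rose in lesional skin, and 12 adjusted over the list alone (camera adjusted p = 3.46e-06, and adjusted p = 0.1 with an estimated correlation). CCL18 rose by 5.06 (SE 0.88, adjusted p = 0.000675), the cytokine gene IL13 by 3.19 (SE 0.65, adjusted p = 0.00259) and CCL13 by 2.4 (SE 0.58, adjusted p = 0.00795). CCL17 rose by 2.31 (adjusted p = 0.0434) and CCL22 by 2.20 (adjusted p = 0.0281), and their calls were lost in 14 and 2 of 18 fits that left out 1 biopsy. IL4R, a receptor chain for interleukins 4 and 13, rose by 1.56 (SE 0.23, adjusted p = 0.000235), and CCL26 differed by 1.74 (adjusted p = 0.0905) and was called without AD_lesional replicate 5 (2.17, adjusted p = 0.0244) or Healthy replicate 7 (2.15, adjusted p = 0.0348). The TSLP and OX40 axis rose in 3 of 9 members and 5 adjusted over the list alone (camera adjusted p = 0.000205, and adjusted p = 0.35 with an estimated correlation). CRLF2 rose by 2.79 (SE 0.52, adjusted p = 0.00123), IL7R by 1.85 and TRAF3 by 0.56, while TSLP differed by 0.56 (adjusted p = 0.301), TNFSF4 by 0.97 (adjusted p = 0.0966) and TNFRSF4 by 1.26 (adjusted p = 0.117). Without AD_lesional replicate 9, TNFSF4 (1.14, adjusted p = 0.0418) and TNFRSF4 (1.53, adjusted p = 0.0422) were called. JAK-STAT genes rose in 7 of 16 members and 9 adjusted over the list alone, with SOCS1 at 1.65, JAK3 at 1.5 and CISH at 1.09 (camera adjusted p = 2.77e-06, and adjusted p = 0.0994 with an estimated correlation).

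In the Th17 and Th22 axis, 15 of 24 members rose and 1 fell by either adjustment (median 2.97, camera adjusted p = 2.54e-09, and adjusted p = 0.35 with an estimated correlation). The alarmin genes S100A7 and S100A9 rose by 5.52 and 5.38, S100A8 by 4.92 (SE 1.31, adjusted p = 0.0147), and DEFB4A, a defensin gene listed at 0 in 4 of 8 healthy biopsies, was at 112 ± 168 TPM (SD, n = 10). IL22 was listed at 0 in 6 of 8 healthy biopsies and at 2.73 ± 2.52 TPM (SD, n = 10) in lesional skin, and IL36A at 0 in 5 of 8 and at 7.61 ± 11.1 TPM (SD, n = 10). Wound-type keratin and hyperplasia genes rose in 10 of 14 members and 12 adjusted over the list alone (median 3.69, camera adjusted p = 2.54e-09, and adjusted p = 0.35 with an estimated correlation). The protease inhibitor gene SERPINB4 rose by 7.70 (SE 1.45, adjusted p = 0.00145), SPRR2A by 6.81, LCE3A by 6.78, SPRR2B by 6.71 and S100A7A, outside the list, by 6.65. Matrix remodelling enzymes rose in 6 of 16 members and 8 adjusted over the list alone, with MMP12 at 5.83, MMP10 at 4.59 and MMP1 at 3.67 (camera adjusted p = 0.000536, and adjusted p = 0.35 with an estimated correlation). Cornified envelope genes had 1 of 28 members higher, TGM3 at 2.05 (camera adjusted p = 0.654, and adjusted p = 0.948 with an estimated correlation). FLG differed by -1.02 (adjusted p = 0.445) and LOR by -1.31 (adjusted p = 0.346). Both were called lower without Healthy replicate 7, at -2.02 (adjusted p = 0.0216) and -2.27 (adjusted p = 0.0313).

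T cell genes rose in 10 of 15 members over all genes and 15 adjusted over the list alone, with CD28 at 2.11 and SH2D1A at 1.98 (camera adjusted p = 4.93e-09, and adjusted p = 0.367 with an estimated correlation). Regulatory T cell and checkpoint genes rose in 8 of 13 members and 9 adjusted over the list alone, with IL2RA at 2.59, TNFRSF9 at 2.13 and TIGIT at 2.11 (camera adjusted p = 5.57e-06, and adjusted p = 0.35 with an estimated correlation). The Th1 axis rose in 4 of 17 members and 8 adjusted over the list alone (camera adjusted p = 3.52e-06, and adjusted p = 0.421 with an estimated correlation). CCL3 rose by 2.82, IL12RB1 by 1.81 and IL12RB2 by 1.27, while CXCL9 differed by 1.81 (adjusted p = 0.179), CXCL10 by 2.10 (adjusted p = 0.151), CXCL11 by 2.25 (adjusted p = 0.0756) and CCL5 by 1.06 (adjusted p = 0.205). CXCL11 was called without AD_lesional replicate 9 (2.57, adjusted p = 0.0385), and IFNG without AD_lesional replicate 3 (adjusted p = 0.0286) or Healthy replicate 6 (adjusted p = 0.0423). Interferon-stimulated genes rose in 8 of 23 members and 14 adjusted over the list alone, with OASL at 2.79, and antigen presentation genes in 5 of 23 and 15, with TAP2 at 1.08. Their camera adjusted p-values were 2.59e-07 and 4.59e-08, with adjusted p = 0.462 and 0.421 with an estimated correlation. GZMB, a cytotoxic protease gene, rose by 2.77 (SE 0.84, adjusted p = 0.0296), a call lost in 5 of 18 fits without 1 biopsy, and TGFB1 rose by 0.93 (SE 0.22, adjusted p = 0.00689). COL1A1 (-0.29), COL3A1 (-0.02) and CTGF (-0.43) were not called.

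Further lists called higher in lesional skin were macrophages (1 of 16 rose, MSR1 at 1.58), cytotoxic cells (2 of 16), dendritic cells (2 of 16, CCR7 at 2.17 and FSCN1 at 1.27), proliferation (0 of 14), matrix (2 of 27, TNC at 1.95 and COL6A3 at 1.19) and keratinocytes (2 of 16 rose and KRT15 fell by 1.73). Their camera adjusted p-values were 0.000191, 0.00108, 0.00129, 0.00838, 0.0238 and 0.0441, with adjusted p = 0.462, 0.615, 0.462, 0.723, 0.723 and 0.723 with an estimated correlation. Sebaceous gland genes fell in 5 of 13 members and 10 adjusted over the list alone, with DGAT2L6 at -5.75, ELOVL3 at -4.59 and PNPLA5 at -4.19 (camera adjusted p = 3.63e-05, and adjusted p = 0.462 with an estimated correlation). PM20D1 (-5.59), SEC14L6 (-5.29), C10orf129 (-5.19), the Wnt inhibitor gene WIF1 (-5.01), ROS1 (-4.87) and C1orf158 (-4.38) also fell. The call of PM20D1 was lost in 13 of 18 fits without 1 biopsy, and that of DGAT2L6 in 11. Mitochondrially encoded genes fell in 1 of 13 members, MT-CYB at -0.67, and 4 adjusted over the list alone, and ribosomal protein genes in 0 of 30 (camera adjusted p = 0.000278 and 0.00129, and adjusted p = 0.462 and 0.723 with an estimated correlation). Adipocyte genes (0 of 13 passed, median 0.48, camera adjusted p = 0.712) and hair follicle genes (0 of 20, median -1.43, camera adjusted p = 0.0584) were not called.

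The third comparison asked whether atopic skin without lesions already differed from healthy skin. Few single genes passed: 59, of which 40 were higher and 19 lower. IL26, a cytokine gene of Th17 cells, was listed at 0 in 4 of 8 healthy biopsies and at 1.57 ± 1.23 TPM (SD, n = 7) in non-lesional skin, and the cornified envelope gene SPRR2G was at 5360 ± 7750 TPM (SD, n = 7) against 253 ± 273 TPM (SD, n = 8). The transcription cofactor gene EID1 rose by 1.17 (SE 0.16, adjusted p = 0.000776), and its call held in all 15 fits that left out 1 biopsy. The kinase gene HIPK3 rose by 1.02 (SE 0.18, adjusted p = 0.0203), B3GNT3 by 1.67, ZC3H12D by 1.37, NECAB1 by 1.20 and DENND1B by 0.95. Of called genes with a mean TPM of at least 1 in either group, those that fell most were PKMP3 at -1.4, ZNF594 at -1.34, ZNF135 at -1.19, ZNF667 at -1.17, ZNF232 at -1.07, ZNF667-AS1 at -1.05, ZBTB12 at -0.94 and QRICH2 at -0.91.

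No member of a list except IL26 passed over all genes in non-lesional skin, but Th2 genes had a median of 0.97 with 5 of 17 higher adjusted over the list alone. Th17 and Th22 genes had a median of 1.29 with 4 of 24 higher adjusted over the list alone, and hyperplasia genes a median of 1.87 with 3 of 14. T cell genes had a median of 1.10 with 2 of 15. Camera called these 4 lists (adjusted p = 0.000142, 1.81e-05, 3e-06 and 5.65e-07), with adjusted p = 0.488, 0.635, 0.635 and 0.635 with an estimated correlation. Adipocyte genes (median 1.66, 0 of 13 by either adjustment) and smooth muscle genes (median 0.86, 1 of 13 higher adjusted over the list alone) were called higher and hair follicle genes (median -1.48, 0 of 20) lower. Their camera adjusted p-values were 3.83e-05, 2.06e-05 and 0.00229, with adjusted p = 0.635, 0.635 and 0.673 with an estimated correlation. CCL18 differed by 4.04 with an adjusted p of 0.0548 and was called without Healthy replicate 7 (4.54, adjusted p = 0.0361), IL13 by 2.28 (adjusted p = 0.149) and S100A8 by 2.62 (adjusted p = 0.499). The gene count was unstable, from 1 without AD_nonlesional replicate 5 to 124 without AD_nonlesional replicate 2, and it was 1 on log2(TPM + 1) and 953 with array weights. Most of the named calls were unstable too. Of the 15 fits that left out 1 biopsy, the call was lost in 13 for PKMP3 and ZNF667, 12 for ZNF667-AS1, 11 for NECAB1, 10 for B3GNT3, ZC3H12D and QRICH2, 9 for DENND1B, ZNF594 and ZBTB12, 8 for SPRR2G, 7 for IL26, 6 for ZNF135, 4 for ZNF232 and 1 for HIPK3.

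The fourth comparison set lesional against non-lesional skin of atopic dermatitis. Without regard to donor, limma called 0 genes, with 2005 at an unadjusted p below 0.05. With the donor as a random block it called 2093, 1088 higher and 1005 lower, and with the donor as a fixed block over the 7 donors with both biopsies it called 96, 82 higher and 14 lower. In the fixed block fit, 11 of 14 genes of the thickened epidermis and 8 of 24 of the Th17 and Th22 axis were higher in lesional skin, and 0 of 13 sebaceous gland genes passed over all genes. With the random block the cytokine gene IL36A rose by 3.55 (SE 0.6, adjusted p = 0.00214) and the elastase inhibitor gene PI3 by 3.05 (SE 0.73, adjusted p = 0.0116).

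In the fixed block fit, 11 of 14 wound-type keratin and hyperplasia genes rose over all genes and 14 adjusted over the list alone (median 1.84, camera adjusted p = 9.71e-18, and adjusted p = 0.286 with an estimated correlation). KRT6C rose by 3.68 (SE 0.24, adjusted p = 0.000527), LCE3A by 2.86 and KRT16 by 2.74. Th17 and Th22 genes rose in 8 of 24 members, with 16 higher and 1 lower adjusted over the list alone (median 1.38, camera adjusted p = 1.49e-12, and adjusted p = 0.286 with an estimated correlation). IL36A rose by 3.59, DEFB4A by 3.28 and PI3 by 3.09 in this fit. Of 17 Th2 genes, 2 rose by either adjustment, CCL22 by 1.28 (SE 0.22, adjusted p = 0.0435) and IL4R by 0.90 (SE 0.15, adjusted p = 0.0399), with camera at adjusted p = 0.00138, and adjusted p = 0.433 with an estimated correlation. Interferon-stimulated genes rose in 1 of 23 members, OASL at 1.97, and in 19 adjusted over the list alone. Proliferation genes rose in 0 of 14 and 13 adjusted over the list alone, Th1 genes in 0 of 17 and 9, and T cell genes in 0 of 15 and 11. Camera gave these 4 lists adjusted p = 4.6e-10, 4.09e-10, 8.64e-07 and 8.64e-07, each with adjusted p = 0.433 with an estimated correlation. Among 28 barrier genes, IVL rose by 1.44 and FLG fell by 0.89 (SE 0.12, adjusted p = 0.0255), and 3 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.196, and adjusted p = 0.714 with an estimated correlation). FLG was not called with the random block (-0.88, adjusted p = 0.289).

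Sebaceous gland genes had 0 of 13 members past the threshold over all genes in the fixed block fit and 11 lower adjusted over the list alone (median -3.99, camera adjusted p = 4.68e-07, and adjusted p = 0.433 with an estimated correlation). With the random block DGAT2L6 (-5.74), AWAT1 (-5.57), AWAT2 (-4.56), AADACL3 (-5.92), PM20D1 (-5.08), SEC14L6 (-5.02), CYP4F8 (-4.39) and ROS1 (-4.25) fell. The largest rises in that fit, besides IL36A and PI3, were SPRR2C (3.6), KRT6C (3.46), SPRR3 (3.33), KRT16P3 (3.19), DEFB4A (3.14) and MMP1 (3.06). CRLF2 rose by 1.22 (adjusted p = 0.0262), CCL22 by 1.25 (adjusted p = 0.0395), IL4R by 0.89 (adjusted p = 0.00245), GZMB by 1.88 (adjusted p = 0.0179) and TGFB1 by 0.51 (adjusted p = 0.0355). With the fixed block CCL22, IL4R and GZMB were called, but CRLF2, TGFB1, SPRR3 and the 8 genes given as falling with the random block were not. Without the block, camera called 23 lists, 15 higher and 8 lower, and 0 with an estimated correlation (smallest adjusted p = 0.505 with an estimated correlation). Among them were sebaceous genes (median -4.12), adipocyte genes (median -1.87) and red blood cell genes (median -2.59, 4 of 5 lower adjusted over the list alone).

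The fifth comparison set sclerotic skin against lesional atopic skin, to ask what separates the diseases. The Th2 genes CCL17, CCL18 and IL13 were far lower in sclerotic skin: CCL17 was at 2.06 ± 3.33 TPM (SD, n = 7) against 96.2 ± 145 TPM (SD, n = 10), and 42.9-fold lower by the fitted log2 fold change. Of the genes of the thickened epidermis 11 of 14 were also lower, and of the regulatory T cell and checkpoint genes 4 of 13. TSLP, TNFSF4 and CXCL9 were higher, with TSLP at 1.95 ± 0.796 TPM (SD, n = 7) against 0.781 ± 0.376 TPM (SD, n = 10), and CRLF2 was lower. Limma called 5467 genes, 2981 higher and 2486 lower, of which 2047 had an absolute log2 fold change of at least 1. It called 2484 with the adipocyte covariate, and 3523 of 13954 genes with GC content and length corrected against 4394 of the same genes uncorrected. The split was 2070 higher and 3287 lower with centred biopsies and 3593 higher and 1306 lower on log2(TPM + 1).

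In sclerotic skin 11 of 17 Th2 genes fell and 1, IL33 (1.62), rose, with 14 lower and 1 higher adjusted over the list alone (median -2.28, camera adjusted p = 2.96e-07, and adjusted p = 0.0706 with an estimated correlation). CCL17 fell by 5.42 (SE 0.79, adjusted p = 2.21e-05), CCL18 fell by 4.89 (SE 0.91, adjusted p = 0.000282) and IL13 fell by 4.54 (SE 0.67, adjusted p = 2.58e-05). CCL22 (-4.2), CCL26 (-3.26) and IL4R (-1.32) fell too. The TSLP and OX40 axis split, with 2 of 9 members higher and 4 lower over all genes, and 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.222, and adjusted p = 0.798 with an estimated correlation). TSLP rose by 1.23 (SE 0.36, adjusted p = 0.0123) and TNFSF4 by 1.22 (SE 0.41, adjusted p = 0.0255), whereas CRLF2 fell by 3.12 (SE 0.54, adjusted p = 0.000129) and IL7R fell by 1.79 (SE 0.54, adjusted p = 0.0153). TNFSF4 lost its call without ScGVHD replicate 1 (0.96, adjusted p = 0.078), 3 (1.00, adjusted p = 0.0755) or 5 (1.06, adjusted p = 0.0574). TNFRSF4 differed by -0.79 (adjusted p = 0.303).

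Of the Th1 axis 2 of 17 members rose, CXCL9 by 3.21 (SE 0.93, adjusted p = 0.0112) and the Th1 transcription factor gene TBX21 by 1.57, and 1 adjusted over the list alone. The list was not called (camera adjusted p = 0.137, and adjusted p = 0.798 with an estimated correlation). CXCL10 differed by 1.43 (adjusted p = 0.306), CXCL11 by 2.23 (adjusted p = 0.0591), IFNG by 1.85 (adjusted p = 0.0975) and CCL5 by 1.33 (adjusted p = 0.0844). Without ScGVHD replicate 4, CXCL11 (2.9, adjusted p = 0.0122), IFNG (2.62, adjusted p = 0.0102) and CCL5 (1.72, adjusted p = 0.0241) were called, and CXCL11 also without ScGVHD replicate 7 or AD_lesional replicate 2 or 10. Interferon-stimulated genes had a median of -0.04, with 1 of 23 higher and 1 lower (camera adjusted p = 0.828). JAK-STAT genes fell in 6 of 16 members, and 7 fell and 1 rose adjusted over the list alone, with SOCS3 at -1.71, SOCS1 at -1.68 and CISH at -1.65 (camera adjusted p = 0.068, and adjusted p = 0.651 with an estimated correlation).

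Th17 and Th22 genes fell in 16 of 24 members and 18 adjusted over the list alone, hyperplasia genes in 11 of 14 and 13, and proliferation genes in 6 of 14 and 10. Their medians were -2.57, -3.8 and -1.02 (camera adjusted p = 2.96e-07, 2.96e-07 and 7.42e-05, each with adjusted p = 0.651 with an estimated correlation). SERPINB4 (-8.24), S100A7A (-8.23), SPRR2A (-8.14), SPRR2F (-8.1), LCE3A (-7.62), DEFB4A (-6.79), IL20 (-5.28) and S100A8 (-4.6) fell. IL36A was at 0 in 5 of 7 sclerotic biopsies, IL22 in 6 of 7 and TGM6 in 4 of 7. Dendritic cell genes fell in 7 of 16 members by either adjustment, with CD1B at -3.49, CCL19 at -2.57 and CCR7 at -2.46. Regulatory T cell and checkpoint genes fell in 4 of 13, with CCR8 at -2.38, TNFRSF18 at -2.36 and FOXP3 at -1.94. Keratinocyte genes fell in 5 of 16 members and 6 adjusted over the list alone, with KRT14 at -2.14, mast cell genes in 4 of 10 by either adjustment, with CTSG at -1.91, and T cell genes in 2 of 15, CD5 and CD6. Camera called these 5 lists lower (adjusted p = 0.000296, 0.0118, 0.00116, 0.0176 and 0.00963), with adjusted p = 0.651, 0.776, 0.651, 0.776 and 0.798 with an estimated correlation. Stress genes fell in 5 of 17 members by either adjustment and hair follicle genes in 0 of 20 (camera adjusted p = 0.00806 and 0.00256, and adjusted p = 0.651 and 0.776 with an estimated correlation).

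Adipocyte genes rose in 11 of 13 members and 12 adjusted over the list alone, with ADIPOQ at 4.19, PCK1 at 4.08 and CIDEC at 3.95, and C14orf180, outside the list, rose by 4.12. The TGF-beta axis rose in 7 of 17 members and 8 adjusted over the list alone, with INHBA at 1.9, CTGF at 1.53 and LTBP2 at 1.52, while TGFB1 fell by 0.79 (SE 0.23, adjusted p = 0.0104). Matrix genes rose in 5 of 27 members by either adjustment, with SFRP4 at 4.40, CTHRC1 at 1.89 and FN1 at 1.85, and COL1A1 (0.68) and COL3A1 (0.76) were not called. Macrophage genes rose in 4 of 16 by either adjustment, with FCGR1A at 2.78, and Schwann cell genes in 5 of 10, with SCN7A at 2.45. Smooth muscle genes rose in 5 of 13 members and 6 adjusted over the list alone, and endothelial genes in 5 of 12, with 1 lower, and 6 adjusted over the list alone. Camera gave these 7 lists adjusted p = 0.000175, 0.0108, 0.0254, 0.0486, 0.00387, 0.00963 and 0.0282, with adjusted p = 0.651, 0.651, 0.798, 0.798, 0.651, 0.776 and 0.776 with an estimated correlation. The osteopontin gene SPP1 rose by 4.97 (SE 1.05, adjusted p = 0.000928), the macrophage chitinase gene CHIT1 by 4.42 (SE 0.91, adjusted p = 0.000707) and the complement gene C6 by 3.97. CIDEC lost its call in 6 of 17 fits that left out 1 biopsy, C14orf180 in 5 and ADIPOQ in 1. The fold changes fell with GC content (r = -0.36 across 13954 genes).

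The sixth comparison set sclerotic against non-lesional atopic skin, which lacks the lesions of eczema. Of Th2 genes 7 of 17 were lower and of Th1 genes 4 of 17 higher in sclerotic skin, with CXCL9 at 115 ± 132 TPM (SD, n = 7) against 2.62 ± 2.03 TPM (SD, n = 7), and 23.3-fold higher by the fitted log2 fold change, by which CCL17 was 26.0-fold lower. TSLP and TNFSF4 were higher and CRLF2 was lower, and 4 of 13 sebaceous gland genes were lower. Limma called 1892 genes, 987 higher and 905 lower, with 703 at an absolute log2 fold change of at least 1, and the split was 690 higher and 1149 lower with centred biopsies and 786 higher and 315 lower on log2(TPM + 1). The count was 874 without AD_nonlesional replicate 4, 1139 without AD_nonlesional replicate 7 and 352 with only the 2 groups in the fit. With GC content and length corrected it was 356 of 13954 genes, and 1634 of the same genes without the correction.

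The Th2 axis fell in 7 of 17 members, with IL33 higher, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 7.53e-06, and adjusted p = 0.157 with an estimated correlation). CCL17 fell by 4.70 (SE 0.86, adjusted p = 0.00178), CCL18 fell by 3.86 and IL13 fell by 3.63 (SE 0.73, adjusted p = 0.00337), as did CCL22 (-3.0) and CCL26 (-2.85). The Th1 axis rose in 4 of 17 members and 9 adjusted over the list alone (camera adjusted p = 8.04e-05, and adjusted p = 0.649 with an estimated correlation). CXCL9 rose by 4.54 (SE 1.01, adjusted p = 0.00681), CXCL11 by 3.76, TBX21 by 2.09 and CCL5 by 2.02, and the call of CCL5 was lost in 9 of 14 fits without 1 biopsy. IFNG differed by 2.58 (adjusted p = 0.0659) and CXCL10 by 3.02 (adjusted p = 0.0778), and both were called without ScGVHD replicate 4, at 3.35 (adjusted p = 0.0102) and 3.83 (adjusted p = 0.018). In the TSLP and OX40 axis 2 of 9 members rose and 1 fell by either adjustment, with a median of -0.04 and a mean of 0.02 (camera adjusted p = 0.847, and adjusted p = 0.95 with an estimated correlation). TNFSF4 rose by 1.65 (SE 0.44, adjusted p = 0.0187) and TSLP by 1.64 (SE 0.39, adjusted p = 0.0108), and CRLF2 fell by 1.94 (SE 0.58, adjusted p = 0.0335), a call lost in 5 of 14 fits without 1 biopsy.

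Sebaceous genes fell in 4 of 13 members and 10 adjusted over the list alone, with PNPLA5 at -5.47, KRT79 at -5.17 and HSD3B1 at -4.29. Hyperplasia genes fell in 3 of 14 members and 4 adjusted over the list alone, with SERPINB4 at -5.84 and SPRR2A at -5.73, and Th17 and Th22 genes in 3 of 24 by either adjustment, with IL20 at -4.05 and IL26 at -3.67. Stress genes fell in 2 of 17 by either adjustment, EGR2 and IER3. Camera called these 4 lists lower (adjusted p = 7.53e-06, 0.000175, 0.000365 and 0.000641), each with adjusted p = 0.649 with an estimated correlation. Macrophage genes rose in 3 of 16 members by either adjustment, with FCGR1A at 3.65, matrix genes in 3 of 27, with SFRP4 at 3.85, FN1 at 1.59 and THBS1 at 1.55, and TGF-beta genes in 4 of 17, with INHBA at 1.9. Camera called these 3 lists higher (adjusted p = 0.00102, 0.00226 and 0.00444), each with adjusted p = 0.649 with an estimated correlation. Adipocyte genes had 0 of 13 members past the threshold by either adjustment, with a median of 1.45 (camera adjusted p = 0.029, and adjusted p = 0.698 with an estimated correlation). SPP1 (3.71), CHIT1 (3.63), RGS4 (3.47) and COX20P1 (4.24) rose, and S100A7A (-6.1), CYP4F8 (-5.89), SPRR2F (-5.5) and DMBX1 (-4.94) fell. The calls of COX20P1, SPP1, CYP4F8, SPRR2F, S100A7A and SPRR2A were lost in 11, 10, 8, 7, 4 and 3 of 14 fits without 1 biopsy, those of CCL26, KRT79, PNPLA5 and SERPINB4 in 2, and that of DMBX1 in 1. The fold changes fell with GC content (r = -0.37 across 13954 genes).

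The fold changes of sclerotic and of lesional skin, each against healthy skin, correlated at r = 0.45 across genes, with a covariance of 0.277. Both use the same healthy biopsies, and unchanged groups simulated against them gave a mean r of 0.5 (-0.36 to 0.85 in 100 simulations) and a mean covariance of 0.078. With the healthy biopsies split between the comparisons, r was 0.28 on average (0.17 to 0.36 in 35 splits) and the covariance 0.193. In both comparisons 477 genes were called higher and 210 lower, and 64 were called in opposite directions. Independent lists of these sizes would share 153 higher and 106 lower genes, values that take no account of the shared healthy biopsies. IL4, IL31 and IL17A were found only in the TPM table and were not called on log2(TPM + 1). Their adjusted p-values were 0.835, 0.952 and 0.638 for sclerotic against healthy skin, 0.682, 0.174 and 0.381 for lesional against healthy skin, and 0.378, 0.153 and 0.0762 for sclerotic against lesional skin.

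**Figure D4:**
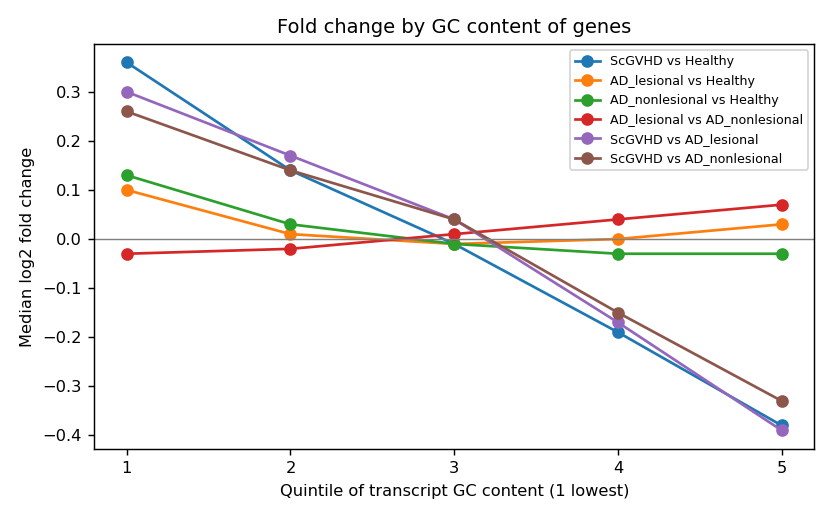
Median log2 fold change of genes (vertical axis) in 5 bins of transcript GC content from lowest to highest (horizontal axis), with 1 line per comparison. For sclerotic against healthy skin it goes from 0.36 in the bin of lowest GC content to -0.38 in that of highest, and for lesional against healthy skin from 0.10 to 0.03.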

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

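The GC and length correction, the adipocyte covariate and the comparison of sebaceous with keratinocyte genes were tests chosen only after the fold changes had been seen. The values below are those of a sample that stood apart from its group: the gap between the highest or lowest biopsy and the next, divided by the range of the group. A value was singled out where this ratio was above Dixon's critical value for the size of the group. Of 536 groups of values tested, 62 passed, 18 at the high end and 44 at the low end, and chance alone passes about 1 in 20. The values of genes are on the log2 scale, where low values spread widely.

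In 1 of 8 healthy biopsies 13 values were lowest by this measure, sebaceous gland genes among them: AADACL3 (0.8082), AWAT1 (0.7445), AWAT2 (0.7980), C10orf129 (0.5261), CYP4F8 (0.6779), DGAT2L6 (0.6038), DMBX1 (0.5354), ELOVL3 (0.6705), KRT79 (0.5932), PM20D1 (0.7098), PNPLA5 (0.5373), ROS1 (0.7158) and the sebaceous gland list (0.6563). Another healthy biopsy was lowest in FLG (0.7917), LOR (0.7571) and the barrier list (0.8087). It was highest in CHIT1 (0.6564), the list of mitochondrial genes (0.6744), the share of TPM in mitochondrial genes (0.7897) and the share in the 10 most abundant genes (0.7428). A further one was highest in CTGF (0.5324), DEFB132 (0.8567) and the adipocyte list (0.7107). Lowest values of other healthy biopsies were CXCL9 (0.5558) and the sweat gland list (0.7819).

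Among the 7 non-lesional biopsies, 1 was lowest in AADACL3 (0.6172), AWAT1 (0.7587), AWAT2 (0.6325), DGAT2L6 (0.6819), KRT79 (0.5687), PM20D1 (0.5870) and PNPLA5 (0.5870), and highest in SPRR2G (0.6373) and the mast cell list (0.5920). Another was lowest in CCL18 (0.6445), CXCL11 (0.5861), MMP1 (0.5905), MMP12 (0.7002), RGS4 (0.6067), SERPINB4 (0.5862) and the proliferation list (0.6671). A further one was highest in the Schwann cell list (0.5927) and in total reads (0.6075). Among the 10 lesional biopsies, C1orf158 had a high value (0.5423), and low values were those of CHIT1 (0.5406), IL26 (0.5740), LCE3A (0.5059), MMP12 (0.5836), TGM6 (0.5769) and WIF1 (0.5198).

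In sclerotic skin 1 of 7 biopsies was lowest in FLG (0.6545), LOR (0.6963), the barrier list (0.6724), the epidermal lipid list (0.7127) and the keratinocyte list (0.8074). Single biopsies were highest in C1orf158 (0.6216), DEFB4A (0.7275), DMBX1 (0.6475), HIPK3 (0.6052), IL22 (0.7257) and SPRR2C (0.8560), and 1 was lowest in COX20P1 (0.5967).

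Of the genes that stand only in the TPM table the report gives just IL4, IL31 and IL17A, and its counts of genes include none of them, yet some of these genes differed from the healthy biopsies. Among 14116 such genes, limma on log2(TPM + 1) called 215 for sclerotic and 60 for lesional against healthy skin. It called 426 for sclerotic against lesional and 77 for sclerotic against non-lesional skin, and 0 for non-lesional against healthy and for lesional against non-lesional skin, with 618 and 466 at an unadjusted p below 0.05.

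The first pattern weighed is that fold changes of sclerotic against healthy skin fell as the GC content of genes rose. The correlation across genes was -0.39 among 2260 long non-coding RNA genes and -0.4 among 11533 coding genes, which is what a GC bias of the libraries predicts, and it may therefore be technical in part. Among 124 pseudogenes it was -0.02 (-0.2 to 0.15). More fat in the sclerotic biopsies was argued against as the source, since the correlation among coding genes was -0.47 (-0.49 to -0.46) with the mean of the adipocyte list as a covariate. Both intervals treat genes as independent replicates and do not measure the spread between biopsies, so this holds for the fitted fold changes only. All 7 sclerotic biopsies had a negative correlation of their own (mean -0.26, SD 0.13) against 3 of 8 healthy ones, and the labels give no batch, so a biological source in the disease stays open and untested.

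The second pattern is that adipocyte genes were higher and skin appendage genes lower in sclerotic skin. Dilution of the biopsy by fat predicts that all other cell types fall alike, but the median of the sebaceous list lay -3.7 from that of the keratinocyte list, beyond the sum of their SDs over genes, 2.6. These SDs do not measure the spread between biopsies, so the gap argues against equal dilution for the fitted medians only. In regroupings of the biopsies, the mean fold change of the sebaceous list had an adjusted share of 0.0731 and that of the keratinocyte list 0.39. A GC bias was argued against for the medians, since after the correction the adipocyte median was 3.34 and the sebaceous median -3.9, with 8 of 12 adipocyte genes still called higher. Of appendage genes, however, only 3 of 12 sebaceous and 1 of 14 hair follicle genes were called lower after it, against 6 of 13 and 7 of 20 before. The hair follicle median was -3.15 in place of -3.67. The values before it include members that were not corrected, so these differences cannot be credited to the correction alone. The covariate on the adipocyte list left the sebaceous median at -3.76 and the hair follicle median at -3.61, but took the keratinocyte median from -0.46 to -0.01 and the melanocyte median from -0.7 to 0.34, so dilution by fat stays open above all for those 2 lists. A different body site or depth of the biopsies and a loss of appendages in the disease remain open, since the labels give neither site nor depth.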

How the results depend on the processing

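The voom precision weights, the GC and length correction and the adipocyte covariate were tests chosen only after the data had been seen. Over the named genes, 528 of 614 results of alternatives for sclerotic against healthy skin kept their direction and side of the threshold, 78 lost the call and 7 gained it. For lesional against healthy skin 613 of 648 held, for non-lesional against healthy 579 of 655, for lesional against non-lesional 686 of 747, for sclerotic against lesional 610 of 649, and for sclerotic against non-lesional skin 536 of 616. Calls lost were 26, 68, 0, 22 and 74, and calls gained 9, 8, 61, 15 and 6. For lesional against non-lesional skin 0 of 42 genes were called in the main fit, so no call could be lost there. Genes not called in either fit counted as held, and only 23 of 40 were called for sclerotic against healthy skin. Fits that left out 1 biopsy are not in these counts or in those of lists. For lists, 209, 222, 196, 221 and 195 of 273 held in the unpaired comparisons, and 226 of 312 for lesional against non-lesional skin. List calls lost were 56, 47, 65, 45 and 78 in the unpaired comparisons and 83 for lesional against non-lesional skin. Lists not called in either fit counted as held, and 22 of 39 were called for sclerotic against healthy skin. Of the lists 0 reversed, but a reversal was counted only where both fits called the list. With the adipocyte covariate CIDEC, a member of that list, turned to -0.16 against healthy and -0.35 against lesional skin, and C14orf180, outside it, to -0.02 against lesional skin.

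The counts of genes that moved by over 1.5 times are these, and the cause was not tested except where fewer genes, fewer samples or a stricter threshold explain it. For sclerotic against healthy skin (4083), log2(TPM + 0.1) gave 2666, log2(TPM + 1) over every gene above 0 gave 2382, a log2 fold change of at least 1 gave 1603, the GC and length correction gave 1713 (the same genes uncorrected 3548) and the adipocyte covariate 1571. For lesional against healthy skin (2586), log2(TPM + 1) gave 1355, log2(TPM + 0.1) 1386, every TPM gene 909, array weights 4465 and the fold change limit 1066. For non-lesional against healthy skin (59), each of the 3 TPM settings gave 1, a mean TPM of at least 1 gave 107, only the 2 groups 27, array weights 953, the fold change limit 15, the GC correction 131 and its genes uncorrected 108. For lesional against non-lesional skin (0), array weights gave 9, the random donor block 2093, the fixed block over paired donors 96, the random block with the GC correction 2389 and its genes uncorrected with the block 1696. For sclerotic against lesional skin (5467), the fold change limit gave 2047, the GC correction 3523 (the same genes uncorrected 4394) and the adipocyte covariate 2484. For sclerotic against non-lesional skin (1892), the TPM settings gave 1101, 900 and 767, only the 2 groups 352, the fold change limit 703 and the GC correction 356 (the same genes uncorrected 1634). The random donor block changed no other count by over 1.5 times (3899, 2304, 76, 5296 and 2189 in the other comparisons).

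Centring each biopsy on its median moved the median fold change of all genes from 0.06 to -0.05 for sclerotic against lesional skin, and from 0 to -0.10 against healthy skin. Lists called fell to 0 with an estimated correlation in all 6 comparisons. Fry for a shared direction gave 16 lists for sclerotic against healthy skin, 13 for lesional against healthy, 0 for non-lesional against healthy, 0 for lesional against non-lesional, 13 for sclerotic against lesional and 1 for sclerotic against non-lesional skin, and fry for either direction gave 8, 4, 0, 0, 5 and 1 in the order of the comparisons. The adipocyte covariate left 14 lists for sclerotic against healthy skin. The correlation of the fold changes of both diseases was 0.28 with split controls.

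Leaving out 1 biopsy gave 3283 to 4510 genes for sclerotic against healthy, 1656 to 3170 for lesional against healthy (1656 without AD_lesional replicate 2), 1 to 124 for non-lesional against healthy, 0 to 2 for lesional against non-lesional (2 without AD_lesional replicate 9), 4531 to 5838 for sclerotic against lesional and 874 to 2246 for sclerotic against non-lesional skin (874 without AD_nonlesional replicate 4, 1139 without replicate 7). For non-lesional against healthy skin the count was 19, 124, 22, 1, 14 and 17 without AD_nonlesional replicate 1, 2, 3, 5, 6 and 7, and 105, 26, 9, 93, 23, 14, 23 and 25 without Healthy replicate 1 to 8. The lists called ranged over 17 to 25, 18 to 23, 13 to 25 (13 without Healthy replicate 1), 18 to 23, 14 to 19 and 19 to 25. Each biopsy had 38.98 M reads or more. The simulation recovered 41% of 2-fold changes between sclerotic and healthy skin, so a gene without a call there is not shown to be unchanged.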

Other observations

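The p53 target list was written after EDA2R, ZMAT3 and AEN had been seen among the called genes, and these were left out of it. As a list, targets of p53, the transcription factor that answers DNA damage, tended to be higher in sclerotic than in healthy skin. Of 30 genes, 7 rose and 0 fell, with a median log2 fold change of 0.35. Over all 20496 genes, 2338 were called higher and 1745 lower. MDM2, whose product limits p53, rose by 0.89 (SE 0.14, adjusted p = 0.000104), TP53INP1 by 1.14 (SE 0.17, adjusted p = 3.69e-05), RRM2B by 1.17, RPS27L by 0.77, CCNG1 by 0.73, SPATA18 by 0.62 and TNFRSF10C by 1.59. CDKN1A, the gene of the cell cycle inhibitor p21, differed by -0.22 (adjusted p = 0.513). Other members below 0 included FDXR (-0.5, adjusted p = 0.0754), PLK3 (-0.36, adjusted p = 0.172) and BBC3 (-0.35, adjusted p = 0.262).

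This pattern is a hypothesis: p53 target activity may be higher in sclerotic skin. Calls in the same biopsies prompted the list, and the p-values below are not adjusted for that choice. The tests and regroupings below are therefore not independent support for it. Camera gave the list p = 0.00137, and p = 0.00761 with an estimated correlation, with the median at 0.35. Against non-lesional skin it was p = 0.0118 and 0.0316, but against lesional skin the list did not pass (p = 0.0949, and p = 0.145 with an estimated correlation, and 0.00785 and 0.0502 after the GC and length correction). A GC bias of the libraries was argued against as the whole source, since after the GC and length correction the median over 26 genes was 0.3, with p = 0.000111, and p = 0.00595 with an estimated correlation. However, 4 genes were called in place of 7. These were MDM2, TP53INP1, RRM2B and BAX, and BAX was not called before. RPS27L, CCNG1 and SPATA18 lost their calls, and TNFRSF10C was not among the genes corrected. The mean of the list was above the healthy mean in 7 of 7 sclerotic biopsies and above every healthy biopsy in 6, and with the correction in 6 and 6. The mean difference of 0.37 exceeded that of all other of 100 regroupings (highest 0.27), and 0.28 with the correction (highest 0.25). A change in the mix of cells stays open and was not tested.

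Regroupings of the same biopsies at random were compared with the real groups. For the count of genes, 1 of 100 regroupings, the real one, was as large for sclerotic against healthy skin (4083, highest other 9), lesional against healthy (2586, highest other 534), non-lesional against healthy (59, highest other 0), sclerotic against lesional (5467, highest other 2520) and sclerotic against non-lesional skin (1892, highest other 192). No other drawn regrouping gave as many genes in these comparisons. With 100 regroupings the share for chance is bounded only at 1 of 100, which does not exclude it. The count for non-lesional against healthy skin was also unstable, at 1 without AD_nonlesional replicate 5. For lesional against non-lesional skin without the donor block, all 100 gave as many as the real 0, and the highest other, 3075, points to a structure of the samples, whose source was not examined. These regroupings took no account of the donors. With the donor as a fixed block, 1 of 64 swaps within donors, the real one, called as many as 96 (highest other 1). With the random block it was 1 of 64 with 2087 genes (highest other 993), where the correlation within donors was estimated on every 5th gene, which gave 2087 in place of 2093.

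For the number of lists called by camera with the preset correlation, chance cannot be excluded. Regroupings gave as many in 10 of 100 for sclerotic against healthy skin (22, highest other 25), 32 for lesional against healthy (20, highest other 32), 19 for non-lesional against healthy (20, highest other 28), 9 for lesional against non-lesional (23, highest other 26), 48 for sclerotic against lesional (18, highest other 28) and 8 for sclerotic against non-lesional skin (25, highest other 29). For some single lists the absolute mean log2 fold change exceeded that of every other regrouping. In sclerotic against healthy skin these were the Th1, antigen presentation, TGF-beta, cytotoxic cell, macrophage, adipocyte and smooth muscle lists, all higher. The Th2 list (mean -0.73) and the stress list (mean -1.07) did so too, but were lower. In lesional against healthy skin these were the Th1, Th2, TSLP and OX40, Th17 and Th22, antigen presentation and JAK-STAT lists. The matrix remodelling, hyperplasia and T cell lists did so as well, and all of these were higher in lesional skin. Each list named here had a share adjusted over the lists of 0.0433. In the other comparisons 0 lists reached an adjusted share below 0.05. The smallest was 0.13 for non-lesional against healthy, 0.292 for lesional against non-lesional, 0.0709 for sclerotic against lesional and 0.0975 for sclerotic against non-lesional skin. With 100 regroupings a share cannot be below 1 of 100, so lists can pass the adjustment only when several stand at that floor together. In sclerotic against lesional skin the Th2, Th17 and Th22, TGF-beta, hyperplasia and stress lists stood at it and still did not pass. In sclerotic against non-lesional skin the Th2, TGF-beta, stress and sebaceous lists did so too. The lack of passing lists in these comparisons with sclerotic skin is therefore no evidence of weaker changes. The floor does not account for it in the others. For non-lesional against healthy skin only the smooth muscle list stood at the floor. For lesional against non-lesional skin the lowest share was 2 of 100, for the Schwann cell list, and the Th1 and Th2 lists were at 12.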
